A study of Rattus norvegicus with 24 samples.

How the data were processed

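RNA was measured by poly-A selected RNA-seq in whole lung of 24 male Wistar rats given silica particles at 200 mg/mL or saline into the trachea, with lungs taken at day 14 or day 28 and 6 animals in each of 4 groups. The deposited expression table gives FPKM (fragments per kilobase of transcript, scaled to library size) made by the authors, for 32489 gene IDs in each of the 24 libraries. The authors' deposited table repeats the FPKM values, with a largest difference of 0, and adds for 3 comparisons of 2 groups a log2 fold change, the same change as a linear ratio, a p-value and an FDR; the tool behind them is not stated, and these columns were used to count genes with an FDR under 0.05 by direction and to check the log2 fold change against the ratio of group mean FPKM. Per the submitters' processing notes, cutadapt 4.0, FastQC 0.11.9, HISAT2 2.1.0 and HTSeq 0.9.1 were used with the rat builds Rnor_6.0 and rn6, without the order of the steps or the version of the gene models. Of the gene IDs, 7529 had no gene name and were kept under their ID, 1707 shared a name with another ID, and 25 had a name that reads as a date. Genes were matched by ID, and positions on the genome were not used.

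The FPKM values of a gene moved between libraries in steps, from which whole reads and a gene length were recovered for 100.0% of the genes with a nonzero FPKM, at a tolerance of 0.02 read. The recovered reads came to between 55.06 and 84.6 M (mega) per library. They were used for depth, for the percent of reads on mitochondrial genes and for 1 alternative test, and not for the main test, because they were inferred from the FPKM and are not the authors' own counts. The tests had first been laid out for counts, with the test used here named in advance for the case of a table of FPKM alone.

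Values were analysed as log2(FPKM + 1). The 20856 genes with an FPKM of at least 0.5 in at least 6 libraries were tested with limma 3.58.1 in R 4.3.3 (limma-trend, moderated by empirical Bayes, two-sided), in 1 fit of 4 group means over all 24 libraries without covariates. The 5 contrasts were silica against saline at day 14, silica against saline at day 28, the difference of these silica effects, and day 28 against day 14 within silica and within saline. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in a contrast. Each log2 change is given with the standard error (SE) of the fit, and each mean level with the standard deviation (SD) over 6 libraries. Comparisons of 1 value per library between groups used two-sided exact permutation tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

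The contrasts, the threshold, the rule for naming genes, 35 gene lists (pathways, cell type markers and tissues that a dissected lung can carry) and 15 lung injury genes were fixed before the data were examined. The rule named, at each day, the 10 genes with the largest rise and the 10 with the largest fall among those called, with a mean FPKM of at least 1, no overlap between the libraries of the groups and an assigned gene symbol; 8 and 8 for the difference of the silica effects, without the condition on overlap; 5 and 5 for the time contrasts; and up to 4 members of each list with the smallest p. The exclusion of provisional symbols was widened after values had been seen, to 2 further kinds of provisional name. Names of structural RNA such as RF00577 and RF00030 were not among the excluded kinds and could be named. The genes whose values were examined library by library were also chosen after values had been seen. Lists with at least 5 tested members, 34 of the 35, were tested with camera (preset correlation 0.01), which compares the members with all other genes, and the adjusted p was taken over the lists of a contrast. Beside it stand camera with an estimated correlation, fry, which asks whether the members move on balance in 1 direction, and the number of members past the threshold when adjusted over the list alone. The cartilage list had too few tested members.

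The fit was tested on simulated data: reads were drawn from the observed gene means, spreads and library totals with 200 genes changed. At day 14 it recovered 23.9% of the genes changed 1.5-fold, 52.2% of those changed 2-fold and 81.8% of those changed 4-fold, and 3.67% of its calls were false. At day 28 these shares were 23.9%, 61.2%, 80.3% and 4.35%. It called 0 genes in a contrast where nothing had been changed. Genes were drawn independently, with 1 spread per gene for all groups. These rates therefore do not cover genes that vary together or groups of unequal spread, as in the real libraries. Replicate numbers were the same in every group. The 36 pairs of libraries with the same number in 2 groups had deviations from their group means that correlated at a mean of -0.023, so that the numbers were not taken to pair animals.

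The alternatives were a pseudocount of 0.1, no filter on low values, a stricter filter, the replicate number as a block, an adjusted p under 0.01, a fit of only the groups compared, the other list tests, and each library left out in turn. Others were chosen after the data had been seen: voom on the recovered reads, rescaling of each library to a level median, the first component of the residuals or the percent of mitochondrial reads as a covariate, a correction for transcript length, the saline group of the other day, and sets of libraries left out. Among these sets, 3 saline day 28 libraries with over 5% mitochondrial reads and 1 silica day 28 library high in muscle transcripts were first left out together. After that result was seen, the 3 saline libraries were left out alone, and then the other 3 saline day 28 libraries. A list's value in these comparisons was changed after a first run from its signed p to the mean log2 change of its members minus that of all genes. Alternatives that had been laid out for original counts were not run.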

Results

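Lung RNA was compared between rats given silica particles or saline by instillation into the trachea, at day 14 and day 28, with 6 libraries in each of the 4 groups. Silica is a mineral dust that causes lung inflammation and scarring, and the series is titled as a study of the progression of this fibrosis. The recovered depth was 74.7 M reads ± 8.32 (SD, n = 6) in saline at day 14, 66.7 ± 5.03 in silica at day 14, 61.0 ± 3.33 in saline at day 28 and 64.8 ± 2.24 in silica at day 28. Correlations of log2(FPKM + 1) across genes between libraries of the same group lay between 0.926 and 0.972; genes are not independent replicates.

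The percent of reads on mitochondrial genes was high in saline at day 28. It was 5.29% ± 2.14 (SD, n = 6) in saline at day 28, against 2.50% ± 0.652 in saline at day 14 (exact permutation p = 0.00433), 2.17% ± 0.200 in silica at day 14 and 2.67% ± 0.686 in silica at day 28 (exact permutation p = 0.00649 against saline at day 28). For silica at day 14 the exact permutation p was 0.26 against saline at day 14 and 0.0519 against silica at day 28. Saline day 28 replicates 1, 2 and 6 had 8.58%, 5.28% and 6.91%. The counts of genes called in comparisons that involve the saline day 28 group are therefore also given without these 3 libraries, a choice made after the data had been seen.

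**Figure D1:**
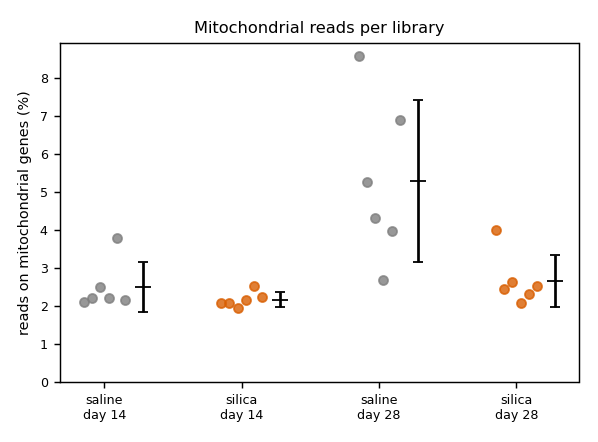
Percent of reads on mitochondrial genes in each library (points, 6 per group), with the mean and SD of each group beside them. The 3 highest libraries, at 8.58%, 6.91% and 5.28%, were all saline at day 28.

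The first comparison asked which genes differed between silica and saline lungs at day 14. The 10 rises and 10 falls named at each day are the largest under the naming rule. It leaves out provisional names and genes whose groups overlap. Scand1, a SCAN-domain protein gene (ENSRNOG00000019987), rose from 5.18 FPKM ± 2.28 (SD, n = 6) to 61.6 ± 27.1, a log2 change of 3.26 (SE 0.404, adjusted p = 1.78e-05). Cebpb, a bZIP transcription factor of inflammatory and macrophage genes, rose by 2.90 on the log2 scale (SE 0.549, adjusted p = 0.00236). The zinc finger gene Zfp771 (ENSRNOG00000043225) rose by 2.75 (SE 0.235, adjusted p = 9.68e-08) and the linker histone gene H1fx (ENSRNOG00000027722) by 2.41 (SE 0.126, adjusted p = 1.43e-11). Frat2, which acts in Wnt signalling, Purb, which binds single-stranded nucleic acid, Taf10, a subunit of the general transcription factor TFIID, and the histone gene Hist2h2aa3 rose by 2.43, 2.37, 2.11 and 2.01. The other 2 of the 10 rises named were in the clock genes Dbp and Nr1d1. In each of these 10 genes every silica library lay above every saline library.

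Among the 10 genes named by the rule for a fall at day 14 was Scd (ENSRNOG00000013552), which encodes stearoyl-CoA desaturase, an enzyme that makes monounsaturated fatty acids. Its level was 97.3 FPKM ± 28.6 (SD, n = 6) in saline and 23.4 ± 8.14 in silica, a log2 change of -2.03 (SE 0.314, adjusted p = 2.89e-04). Pimreg, a mitotic regulator, fell by 1.12 on the log2 scale, and St8sia2, a polysialic acid synthase, fell by 1.11. Mest, an imprinted gene, and Igfbp5, an IGF-binding protein, fell by 1.09 and fell by 1.04, and Cemip2, a cell-surface hyaluronidase, fell by 1.017. Scn3b, Slc28a3, Itga2 and Lmntd1 changed by -0.99, -0.99, -0.98 and -0.95; Itga2 is a collagen-binding integrin subunit and Slc28a3 a nucleoside transporter. Each of these 10 genes was lower in every silica library than in every saline library. Igfbp5 (adjusted p = 0.0411) was no longer called without any 1 saline replicate or without silica replicate 1, 4, 5 or 6, at -1.11 to -0.86, and Slc28a3 (adjusted p = 0.0407) without saline replicate 1, 2, 3, 4 or 6 or silica replicate 1, 4 or 5, at -1.06 to -0.82.

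In total 911 genes were called at day 14, 564 higher and 347 lower with silica, and 108 of the higher and 21 of the lower ones changed by at least 1 on the log2 scale. Groups did not overlap for 1043 genes, or 5.0% of those tested, against 0.216% by chance. Removing saline replicate 4 left 579 calls and removing silica replicate 4 left 576; an adjusted p under 0.01 left 363. With the mitochondrial percent as a covariate 1701 genes were called, 810 higher and 891 lower. With the first residual component, which lowers the spread by construction, there were 1968, 971 higher and 997 lower.

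**Figure D2:**
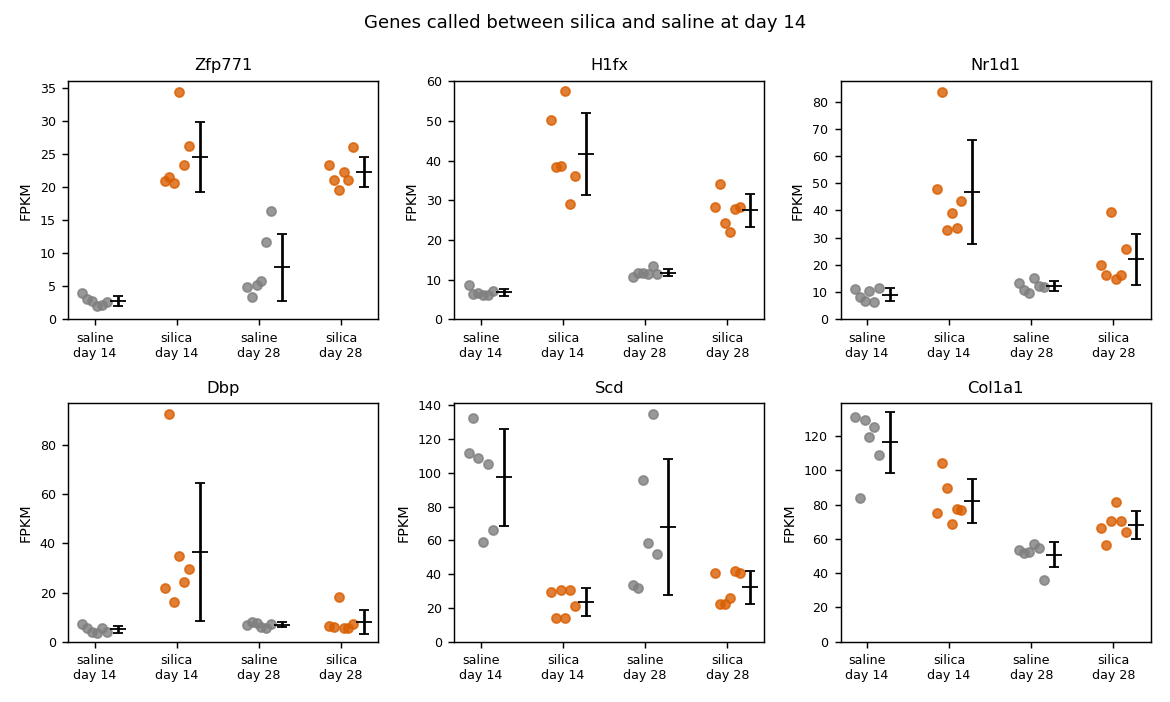
FPKM of 6 genes called between silica and saline at day 14, in each library (points, 6 per group), with the mean and SD of each group beside them. Zfp771 and H1fx stayed higher with silica at day 28, while Dbp had 36.5 FPKM in silica at day 14 and 8.15 at day 28.

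Of the gene lists at day 14, the circadian clock list rose in camera (adjusted p = 0.0291, or 0.599 with an estimated correlation). Without the 3 saline day 28 libraries, which share the fit, the camera adjusted p was 0.0512. Of its 15 tested members 4 were called higher, 1 lower and 10 not. When adjusted over the list alone 10 passed, 7 higher and 3 lower. Dbp, a clock output transcription factor (ENSRNOG00000021027), rose by 2.42 (SE 0.297, adjusted p = 1.65e-05) and Nr1d1, the repressor REV-ERB alpha (ENSRNOG00000009329), by 2.20 (SE 0.223, adjusted p = 1.56e-06). Nr1d2 rose by 1.51 (SE 0.27) and Per3 by 1.08 (SE 0.21). The list's call was also lost without saline replicate 5 and without silica replicate 2. Silica replicate 2 had the highest Dbp, 92.3 FPKM.

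The list of fatty acid synthesis and surfactant lipid fell at day 14 (camera adjusted p = 4.38e-04, or 0.599 with an estimated correlation). When adjusted over the list alone 9 members were past the threshold, 8 lower and 1 higher. Over all genes, 3 of 17 members were called lower, none higher and 14 not. Beside Scd these were Srebf1, the transcription factor of lipid synthesis, at -0.58 (SE 0.12, adjusted p = 0.0051) and Scd2, a second desaturase, at -0.89 (SE 0.21, adjusted p = 0.0135). Of the 20 members of the sterol synthesis list, Idi1 and Cyp51 were called, at -0.47 and -0.51, and 18 were not (camera adjusted p = 0.011; 0.965 with an estimated correlation). Without saline replicate 3, Cyp51 (-0.44) and the sterol list were not called.

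The extracellular matrix list was lower with silica at day 14, with 2 of 22 members called lower, none higher, 20 not, and 8 past the threshold when adjusted over the list alone (camera adjusted p = 1.92e-06; adjusted p = 0.599 with an estimated correlation). Fbn1, the microfibril component fibrillin, fell by 0.68 on the log2 scale (SE 0.12, adjusted p = 0.00109). Col1a1, a chain of type I collagen (ENSRNOG00000003897), had 116 FPKM ± 17.8 in saline and 81.9 ± 12.9 in silica, a log2 change of -0.50 (SE 0.123, adjusted p = 0.0203). Its call was lost without saline replicate 1 or 3 or silica replicate 4, at -0.46, -0.46 and -0.45, and after the length correction, at -0.34.

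Cell cycle genes were lower as a list at day 14 (camera adjusted p = 5.14e-05; 0.92 with an estimated correlation), although none of its 21 members was called over all genes and 7 passed when adjusted over the list alone; Mki67 and Cdk1 had -0.72 and -0.65. Ciliated cell markers, with none of 14 called, and erythroid and blood genes, with Slc4a1 called at -0.76 among 11, were lower as lists (camera adjusted p = 0.00585 and 0.0291; 0.965 and 0.92 with an estimated correlation). The interferon response list was higher with none of 19 members called (camera adjusted p = 0.0339; 0.965 with an estimated correlation), Isg15 having 0.44. Airway secretory and cardiac muscle markers were lower with no member called (camera adjusted p = 0.0431 and 0.0479; 0.965 and 0.965 with an estimated correlation). The call of the ciliated list was lost without saline replicate 5, of the erythroid list and Slc4a1 without saline replicate 3 or silica replicate 1, and of the interferon list without saline replicate 5 or 6 or silica replicate 1, 2, 3 or 4. The call of the secretory list was lost without saline replicate 3 or 5 or silica replicate 1, 3 or 6, and of the cardiac list without saline replicate 3, 4 or 5 or silica replicate 1, 4, 5 or 6. The erythroid list was also lost without silica replicate 5, and Slc4a1 without saline replicate 2 or silica replicate 4, at -0.70 and -0.64. No list passed the estimated-correlation test, and 3 lists, those of matrix, fatty acids and clock, passed fry. Without saline replicate 5, saline replicate 3 or silica replicate 1, 5, 6 and 6 lists passed camera in place of 10.

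The remaining 24 lists at day 14 had adjusted p between 0.141 and 0.958 in camera; some of their members were called singly. Nkx2-1, a transcription factor of lung epithelium, rose by 1.09 (SE 0.16, adjusted p = 1.65e-04), and Sox18, an endothelial transcription factor, by 0.75. The chemokine gene Cxcl12 fell by 0.54 on the log2 scale (adjusted p = 0.0214) and was not called without saline replicate 1 or silica replicate 4, 5 or 6, at -0.52, -0.52, -0.47 and -0.51. Another chemokine gene, Cxcl14, rose by 0.85 (adjusted p = 0.0343), but was not called without saline replicate 1, 2, 3 or 6 or silica replicate 2, 3, 4 or 6, at 0.79 to 0.87. Casp1, the inflammasome protease gene, rose by 0.31 (adjusted p = 0.048) and was not called when any 1 library other than silica replicate 5 was left out, at 0.25 to 0.33.

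Of the 15 lung injury genes named in advance, 14 were tested at each day and Il6 was below the filter. Beside Col1a1, none of these was called at day 14. The cytokine gene Il1b had 0.08 (SE 0.262, adjusted p = 0.90), Tnf 0.12, the inflammasome sensor Nlrp3 0.03, the chemokine Ccl2 -1.24 (SE 0.475, adjusted p = 0.137), Mmp12 -0.79 (adjusted p = 0.124), osteopontin Spp1 -0.59, fibronectin Fn1 -0.59, Timp1 -0.51, Tgfb1 0.25, Acta2 -0.09, the surfactant gene Sftpc 0.21 and the type 1 cell gene Ager 0.29. At day 28 Col1a1 and Col3a1 were called, and the values of Il1b, Tnf, Nlrp3, Ccl2, Mmp12, Spp1, Fn1, Timp1, Tgfb1, Acta2, Sftpc and Ager were -0.18, 0.02, 0.07, 0.64, 0.34, 0.33, 0.41, 0.84, 0.29, 0.14, 0.36 and 0.47, none called. Without the 3 high-mitochondrial saline libraries the same 12 had -0.599, -0.0608, -0.282, 0.0161, -0.19, 0.104, 0.156, -0.252, 0.00668, 0.0908, -0.0153 and 0.163, none called, so that Tnf, Nlrp3, Mmp12, Timp1 and Sftpc turned. Col3a1, a chain of type III collagen, had 576 FPKM ± 89.8 in saline and 895 ± 151 in silica at day 28 (log2 change 0.63, SE 0.137, adjusted p = 0.0085), and Col1a1 a log2 change of 0.42 (SE 0.123, adjusted p = 0.028). Without the 3 libraries these were 0.46 (adjusted p = 0.259) and 0.31 (adjusted p = 0.369), and neither was called. Col1a1 was also not called without saline replicate 1, 2 or 6 or silica replicate 3, 4 or 5, at 0.44, 0.43, 0.33, 0.41, 0.37 and 0.41.

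At day 28 the same question was asked against that day's own saline animals. Among the 10 rises named by the rule were Aqp3, an aquaglyceroporin of epithelia (ENSRNOG00000009797, log2 change 2.49, SE 0.520, adjusted p = 0.00781), and Cebpa, a bZIP transcription factor (2.32, SE 0.639, adjusted p = 0.0226). Silica replicate 1 had 45.5 FPKM of Aqp3 and the other 5 between 2.46 and 16.7. Tmem158, Fam172a, Zfp771, the beta-cell transcription factor gene Mafa and Sox12 rose by 1.88, 1.60, 1.56, 1.42 and 1.41. Angptl4, an inhibitor of lipoprotein lipase, Ccdc71l and Acot3, an acyl-CoA thioesterase, rose by 1.38, 1.37 and 1.36. Of these 10, Tmem158, Zfp771, Sox12 and Ccdc71l were also called without the 3 saline libraries, at 1.5, 1.52, 1.44 and 1.48. Aqp3, Cebpa, Fam172a, Mafa, Angptl4 and Acot3 were not, though at 2.22, 2.66, 1.395, 1.41, 1.23 and 1.285. Cebpa was not called without saline replicate 2, at 1.95, nor Fam172a without saline replicate 1 or 2 or silica replicate 3 or 4, at 1.52, 1.52, 1.42 and 1.41.

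The 10 falls named by the rule at day 28 included the immediate early transcription factor genes Fos and Egr1. Fos had 23.1 FPKM ± 9.27 in saline and 4.92 ± 1.44 in silica, a log2 change of -1.96 (SE 0.406, adjusted p = 0.00772), and Egr1 changed by -1.55 (SE 0.460, adjusted p = 0.0303). Ddhd1, a phospholipase gene, fell by 1.76 on the log2 scale (SE 0.227, adjusted p = 9.53e-05) and was the only 1 of these 10 also called without the 3 saline libraries, at -1.63 (adjusted p = 0.00476). Rgs1, Tex26, Bok, Pik3r2, RF00577, Junb and Gnrh1 changed by -1.15, -1.09, -1.07, -0.98, -0.95, -0.94 and -0.91. Without the 3 saline libraries these had, in the same order, -1.199, -0.747, -0.988, -0.677, -0.645, -0.918 and -0.426. Fos and Egr1 had -1.95 and -1.64 without the 3 libraries but adjusted p of 0.124 and 0.274. Egr1 was not called without saline replicate 2 or silica replicate 3 or 4, at -1.41, -1.48 and -1.45.

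In all, 2872 genes were called at day 28, 1105 higher and 1767 lower. Groups did not overlap for 609 genes, or 2.92% of those tested, fewer than at day 14. Leaving out the 3 high-mitochondrial saline libraries reduced the calls to 60, of which 53 were among the 2872, whereas leaving out the other 3 saline day 28 libraries raised them to 6345. The excess of lower genes turned around in several settings. There were 43 higher and 17 lower without the 3, and 184 and 157 of 341 at an adjusted p under 0.01. There were 313 and 267 of 580 in the fit of only the groups compared, where the spread comes from the day 28 libraries alone. With the mitochondrial covariate there were 19 and 2 of 21. The median change of the 2872 genes in their own direction was 0.578 (median SE 0.158) with all libraries, 0.368 (0.17) without the 3 and 0.781 (0.173) without the other 3. Single libraries moved the count too: it was 1034, 993 and 4429 without saline replicate 1, 2 and 5, and 1409 and 1421 without silica replicate 3 and 4.

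**Figure D3:**
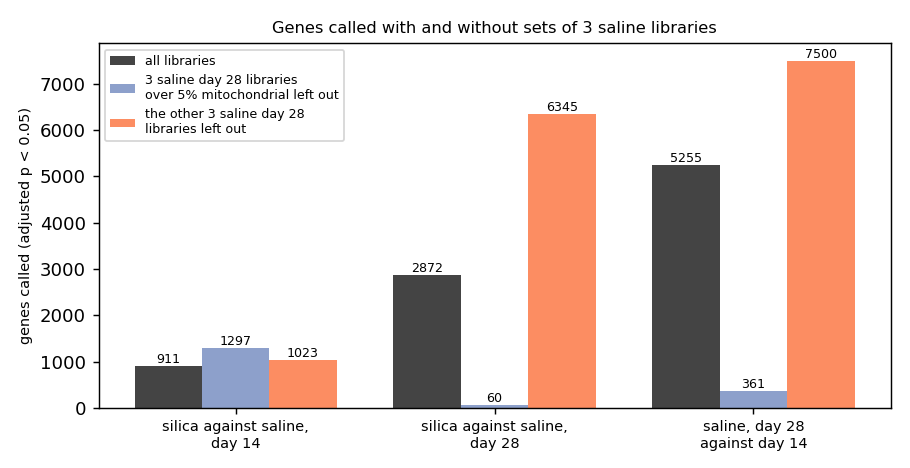
Genes called at an adjusted p under 0.05 in 3 comparisons (bars, axis from 0), with all 24 libraries, without the 3 saline day 28 libraries over 5% mitochondrial reads, and without the other 3. The day 28 count went from 2872 to 60 or 6345, and that of day 14 from 911 to 1297 or 1023. The day 14 comparison holds none of the libraries left out. Its count moved only through the spread that the 4 groups share in the fit.

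With all libraries, 12 gene lists passed camera at day 28. Without the 3 saline libraries none of their members was called over all genes, and 7 lists passed, among them 2 that had not, those of T and NK cells (0.0296) and the inflammasome (0.0373), both downward. The medians of these 2 had turned from 0.203 and 0.0205 to -0.202 and -0.144. All 22 extracellular matrix members were above 0, with 3 called higher, 19 not, and 13 past the threshold when adjusted over the list alone (camera adjusted p = 2.39e-07; adjusted p = 0.659 with an estimated correlation; 2.4e-04 without the 3 saline libraries). Of the matrix metalloproteinase and plasminogen list, Mmp14, Timp3, Mmp2 and Plau rose, by 0.83, 0.81, 0.61 and 0.60 (Plau not without saline replicate 1 or 2, at 0.53 and 0.54), and 11 of 15 were not called (camera adjusted p = 0.0303; 0.683 with an estimated correlation; 0.324 without the 3). Of the TGF-beta and activin list, 3 of 19 members were called higher, among them the receptor gene Tgfbr2 at 0.51, which was not called without saline replicate 1 or 2, at 0.44 and 0.44 (camera adjusted p = 0.0174; 0.659 with an estimated correlation; 0.238 without the 3).

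Ciliated cell markers were lower with silica at day 28: 8 of 14 were called lower, 6 not, and 13 passed when adjusted over the list alone, among them the dynein heavy chain genes Dnah9 at -1.05 (SE 0.26, adjusted p = 0.0142) and Dnah11 at -1.01 (camera adjusted p = 1e-06; 0.659 with an estimated correlation; 3.39e-05 without the 3). The club cell secretory protein gene Scgb1a1 had 36400 FPKM ± 16100 in saline and 15300 ± 6650 in silica at day 28 (log2 change -1.23, SE 0.36, adjusted p = 0.0291). Scgb1a1 was not called without the 3, nor without saline replicate 1 or 2 or silica replicate 3 or 4, at -1.08, -1.08, -1.10 and -1.14. At day 14 its level was 13900 FPKM ± 3200 in saline and 14000 ± 6930 in silica, so that saline at day 28 stood apart. Ciliated markers too rose within saline from day 14 to day 28, as given below. Of 14 immediate early and heat shock genes 7 were called lower (camera adjusted p = 2.08e-04; 0.659 with an estimated correlation; 7.66e-07 without the 3), with Junb at -0.94 and Zfp36, which speeds the decay of cytokine mRNA, at -1.07. Of 10 mitochondrially encoded genes 7 were called lower, in step with the mitochondrial percent above (camera adjusted p = 0.00188; 0.659 with an estimated correlation; 0.0186 without the 3).

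Alveolar type 1 cell markers were higher at day 28, with 3 of 14 called and 8 past the threshold when adjusted over the list alone, among them Akap5 at 0.86, not called without saline replicate 1 or 2, at 0.79 and 0.76 (camera adjusted p = 4.48e-04; 0.683 with an estimated correlation; 0.0574 without the 3). Endothelial, alveolar fibroblast and alveolar type 2 lists were higher with 2 of 19, 3 of 15 and 1 of 14 members called (camera adjusted p = 0.0174, 0.0303 and 0.0303; 0.723 in each with an estimated correlation; 0.378, 0.324 and 0.378 without the 3). The complement and cardiac muscle lists were higher with no member called (camera adjusted p = 0.0303 and 0.0174; 0.723 in both with an estimated correlation; 0.464 and 0.00633 without the 3). Without the 3 the medians of the complement and metalloproteinase lists turned, from 0.221 and 0.225 to -0.131 and -0.0189. Those of the type 2, endothelial, TGF-beta, type 1 and alveolar fibroblast lists went from 0.296, 0.252, 0.161, 0.44 and 0.17 to 0.0834, 0.0405, 0.0766, 0.189 and 0.0863. The matrix, ciliated, immediate early, mitochondrially encoded and cardiac medians went from 0.424, -0.9, -1.02, -0.948 and 1.36 to 0.242, -0.553, -0.929, -0.476 and 1.61. Single libraries ended the calls of the complement list (saline replicate 1, 2 or 6 or silica replicate 5), the type 2 cell list (saline replicate 1 or 2 or silica replicate 5 or 6), the alveolar fibroblast list (saline replicate 2 or 6 or silica replicate 4 or 6), the metalloproteinase list (saline replicate 1 or 6), the TGF-beta list (saline replicate 6) and the cardiac list (silica replicate 1). The remaining 22 lists had camera adjusted p between 0.0646 and 0.985, and fry called 4 lists, those of matrix, ciliated cells, immediate early genes and mitochondrially encoded genes.

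**Figure D4:**
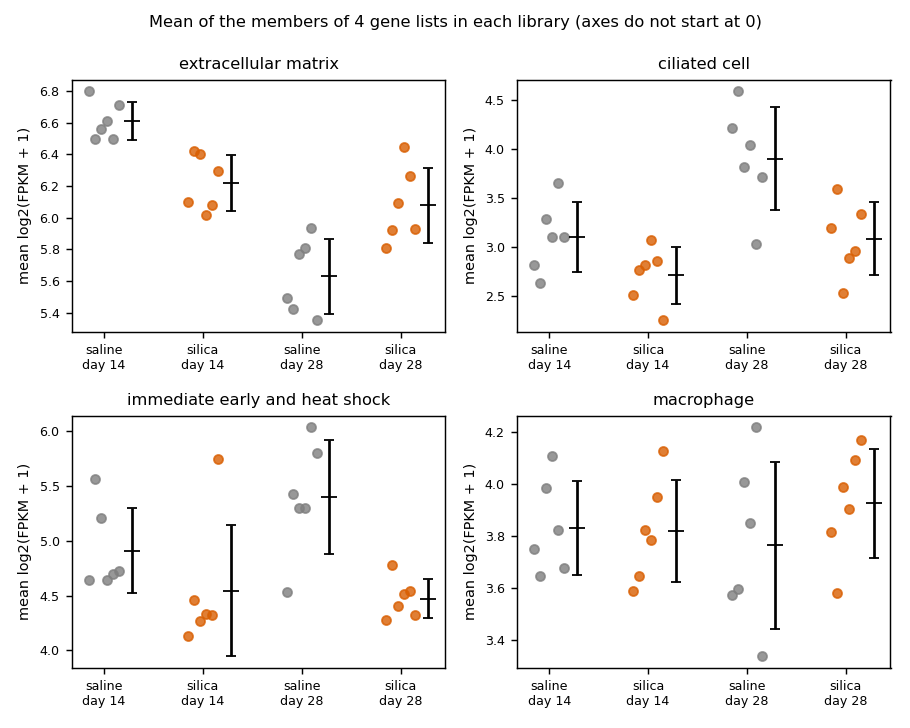
Mean log2(FPKM + 1) over the members of 4 gene lists in each library (points, 6 per group), with the mean and SD of each group beside them; the axes do not start at 0. The matrix list was highest in saline at day 14 and lowest in saline at day 28, with the silica groups between.

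The overlap of the days asked whether the silica response was shared. Of the genes called at both days, 159 were higher at both against 29.9 expected by independence, 20 were lower at both against 29.4, and 43 went in opposite directions against 66.2. Zfp771, Frat2, Sox12, Angptl4 and Ccdc71l were higher at both days. Frat2 had 2.43 and 1.79, Angptl4 1.25 and 1.38, and Ccdc71l 1.60 and 1.37; these examples were chosen after their values were seen. The log2 changes of the 2 days correlated across all genes tested at r = 0.0425, and 55.5% of the day 14 calls had the same sign at day 28. Of the day 28 calls, 49.2% had the same sign at day 14. The 179 shared calls became 40 without the 3 high-mitochondrial libraries, and 114 and 115 without saline day 28 replicate 1 or 2.

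The difference of the silica effects asked which genes responded otherwise at day 28 than at day 14. Matrix genes stood out: 9 of 22 were called with a higher effect at day 28, 13 were not, and 20 passed when adjusted over the list alone (camera adjusted p = 3.23e-12; adjusted p = 0.357 with an estimated correlation). Fbn1, Col1a1 and Col3a1 differed by 1.15, 0.92 and 0.92 (adjusted p = 0.0048, 0.00907 and 0.0115). Without the 3 high-mitochondrial saline libraries 1 matrix gene was called. Col1a1 and Col3a1 were not, at 0.80 and 0.74 (adjusted p = 0.0793 and 0.0951). Saline itself moved: Col1a1 had 116 FPKM in saline at day 14 and 50.8 at day 28, against 81.9 and 68.2 in silica. The water channel gene Aqp1, the anion channel subunit gene Lrrc8a and the interferon signalling gene Irf9 differed by 2.33, 3.05 and 2.34, and Dbp by -2.32 (SE 0.420, adjusted p = 0.00876). Myh9, Pcdhgc3, Palm2, Lrrc4 and Praf2 had positive differences, and RF00030, RT1-N2, Mlc1, Scand1, Tef, Gng13 and Cracr2b negative ones. Without silica day 14 replicate 4, Palm2, Pcdhgc3, Praf2, RF00030, Scand1 and Tef were not called, at 2.39, 2.88, 1.86, -3.29, -1.79 and -1.89, nor without several other single libraries, and Myh9 was not called without saline day 28 replicate 1, at 3.6.

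In total 2071 genes differed, 1048 upward and 1023 downward, and 8 without the 3 high-mitochondrial saline libraries, 1 upward and 7 downward, none of them among the 16 named by the rule. Without those 3 libraries the 16 kept their direction. Irf9 had 2.51 and Dbp -2.24, while RF00030 went from -3.69 to -1.81. The count was 5237 without the other 3, and 1098, 1281, 1220, 1094, 1110, 3286, 1203, 1160, 1185 and 1062 without saline day 14 replicate 1, 2 or 4, saline day 28 replicate 1, 2 or 5, silica day 14 replicate 4 or 5, and silica day 28 replicate 3 or 4. Lists of cell cycle, metalloproteinase, TGF-beta, type 1 cell, sterol, fatty acid and cardiac genes differed upward (camera adjusted p = 8.34e-05, 0.00694, 0.00795, 0.0433, 0.00317, 0.00768 and 0.00316; 0.829, 0.599, 0.599, 0.829, 0.829, 0.599 and 0.829 with an estimated correlation), with 4, 2, 3, 2, 0, 2 and 0 members called higher. Of these 8 lists, matrix, cell cycle and cardiac also passed without the 3 libraries, at 7.49e-10, 0.00283 and 0.00195. In the 7 lists other than matrix no member was called without them. Interferon, T and NK cell, and immediate early lists passed only without the 3, all downward (0.0134, 0.0299 and 0.0357). The type 1 cell median turned from 0.241 to -0.0406 without them. The type 1 cell list's call was lost without saline day 14 replicate 6, saline day 28 replicate 1 or 2, silica day 14 replicate 2, 3 or 4, or silica day 28 replicate 2, 3, 4 or 6. The remaining 26 lists had camera adjusted p between 0.0586 and 0.999.

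Within the silica animals, the time comparison asked what changed from day 14 to day 28. Dbp was the 1 gene called by limma-trend: it went from 36.5 FPKM ± 28.1 (SD, n = 6) at day 14 to 8.15 ± 4.88 at day 28, a log2 change of -1.91 (SE 0.297, adjusted p = 0.0307). It was not called without silica day 14 replicate 4, 5 or 6 or without silica day 28 replicate 1, 2, 4, 5 or 6, where the log2 change lay between -1.98 and -1.85, and voom on recovered reads called 0 genes. At an unadjusted p under 0.05 there were 1838 genes, and the groups did not overlap for 143, or 0.686%. The authors' deposited table holds 140 genes with an FDR under 0.05 for this pair of groups, and 2290 and 3076 for silica against saline at day 14 and day 28. The clock list fell with 1 of 15 members called and 8 past the threshold when adjusted over the list alone (camera adjusted p = 9.93e-04; adjusted p = 0.198 with an estimated correlation). Collagen genes moved by -0.26 in Col1a1 and -0.38 in Col3a1, not called.

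Other lists also passed camera in silica over time without a called member. Ciliated, mesothelial, secretory airway, cell cycle, cardiac and skeletal muscle lists were higher (adjusted p = 5.64e-04, 0.00295, 0.016, 0.00671, 0.00538 and 0.00768), and endothelial, matrix, interferon, mast cell and alveolar type 1 lists were lower (adjusted p = 9.26e-04, 0.00295, 0.00671, 0.00717 and 0.016); with an estimated correlation each had an adjusted p of 0.627. Silica day 28 replicate 1 held muscle transcripts, with 12000 FPKM of Acta1 where the other 5 had 2.36 to 8.16. Without it 4 lists passed in place of 12, and the skeletal muscle list's mean change relative to all genes went from 1.28 to -0.01. Other single silica libraries also ended calls: day 14 replicate 1 those of the type 1 cell and interferon lists, day 14 replicate 2 that of the matrix list, day 14 replicate 6 and day 28 replicate 6 those of the secretory and mast cell lists, and day 28 replicate 3 that of the cell cycle list. The remaining 22 lists had adjusted p between 0.0639 and 0.923. Without the 3 saline libraries, which share the fit, the mitochondrially encoded list passed too, upward (0.0352).

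Within the saline animals, the background of the time comparison, matrix genes fell from day 14 to day 28: 20 of 22 were called lower, none higher and 2 not, and all 22 passed when adjusted over the list alone (camera adjusted p = 2.47e-19; adjusted p = 0.0676 with an estimated correlation). Col3a1 changed by -1.29 (SE 0.137) and Col1a1 by -1.18 (SE 0.123), each at an adjusted p of 1.44e-05, and elastin, Eln, by -1.44. Without the 3 high-mitochondrial libraries 11 matrix genes were called, with Col3a1 at -1.12 and Col1a1 at -1.06, each at an adjusted p of 0.00226. Among the 10 genes named by the rule, Scand1, Cebpb, Cracr2b, Wasf3 and Ccdc190 rose by 1.79, 1.74, 1.72, 1.44 and 1.43, and Palm2, Lrrc8a, Irf9, Aqp1 and Rasgrp3 changed by -2.70, -2.29, -2.18, -1.86 and -1.58. Of these 10, Scand1, Cracr2b, Wasf3, Lrrc8a, Irf9 and Rasgrp3 were also called without the 3 libraries. Cebpb, Ccdc190, Palm2 and Aqp1 were not, at 1.55, 1.03, -2.46 and -1.44.

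In total 5255 genes were called in saline, 2943 higher and 2312 lower at day 28, and 361 without the 3 high-mitochondrial libraries, of which 333 were among the 5255; without the other 3 there were 7500. Without the 3, 161 were higher and 200 lower. With all libraries the groups did not overlap for 1765 genes, or 8.46%. Ciliated markers rose with 11 of 14 called (camera adjusted p = 7.92e-05; 0.521 with an estimated correlation), as did mitochondrially encoded genes with 6 of 10 (0.00332; 0.514 with an estimated correlation) and immediate early genes with 3 of 14 (0.0451; 0.748 with an estimated correlation). Alveolar type 1, endothelial and alveolar fibroblast markers fell with 6 of 14, 9 of 19 and 5 of 15 called lower (camera adjusted p = 9.63e-05, 6.21e-04 and 6.21e-04; 0.514, 0.521 and 0.514 with an estimated correlation). Metalloproteinase, TGF-beta, cell cycle, sterol, fatty acid, complement, mast cell, erythroid and cardiac lists fell too (camera adjusted p = 0.00227, 0.00227, 0.00106, 0.00704, 0.0253, 0.0297, 0.0245, 0.0114 and 0.0262; 0.514, 0.514, 0.591, 0.685, 0.514, 0.721, 0.591, 0.514 and 0.761 with an estimated correlation). Without the 3 libraries the sterol, fatty acid and complement lists did not pass (0.141, 0.226 and 0.598). T and NK cell and mesothelium lists passed only without them, both upward (0.0376 and 0.0232), and the complement median turned from -0.212 to 0.0895. The ciliated, mitochondrially encoded, immediate early, type 1, endothelial and alveolar fibroblast lists passed at 0.00254, 0.0232, 0.0123, 0.0105, 0.0232 and 0.0105, with 0, 0, 1, 1, 0 and 0 members called. Single libraries ended the calls of the immediate early list (saline day 14 replicate 1, 4, 5 or 6 or day 28 replicate 4, 5 or 6), the complement list (day 14 replicate 3 or day 28 replicate 1, 2 or 6) and the cardiac list (day 14 replicate 3 or 5 or day 28 replicate 5). The remaining 18 lists had adjusted p between 0.059 and 0.96.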

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

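The genes and lists below were chosen by the rule fixed in advance, apart from the genes whose values were examined library by library and the library measures, which were chosen after values had been seen.

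In 46 of 288 groups of 6 libraries, the highest or lowest library lay further from its nearest neighbour, as a share of the group's range, than Dixon's limit for 6 values. For independent groups of normal values chance gives about 1 in 20, or 14.4 groups. Single genes were tested on the FPKM scale and several measures of a library overlap, so that the 46 cannot be set directly against this.

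Silica day 28 replicate 1 held muscle transcripts: it had 12000 FPKM of Acta1 (2.36 to 8.16 in the other 5), 2330 FPKM of Ckm (0.29 to 3.33) and 114 FPKM of Myh6, and its skeletal muscle list mean was 9.59 on the log2(FPKM + 1) scale (1.68 to 1.93). It also had 4.01% mitochondrial reads, 45.5 FPKM of Aqp3, and list means of 5.44 for transitional and basal epithelium, 5.4 for lysosome, 6.79 for alveolar type 1 cell, 5.67 for endothelium and 4.58 for alveolar fibroblast, the last 4 below its group. Saline day 14 replicate 5 had 143 FPKM of Myh6, 36.7 FPKM of Ckm, 3.8% mitochondrial reads, 25300 FPKM of COX1 and list means of 9.98 for mitochondrially encoded genes and 3.24 for adipose, all above its group.

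Silica day 14 replicate 2 was above its group in Dbp, at 92.3 FPKM (16.1 to 34.8), and Nr1d1, at 83.7 FPKM, and silica day 28 replicate 3 in Dbp, at 18.1 FPKM (5.72 to 7.06). Silica day 14 replicate 6 was above its group in Fos (32.7 FPKM), Egr1 (114 FPKM), Tnf (2.55 FPKM), Aqp3 (15.2 FPKM) and the immediate early list (5.75). Silica day 28 replicate 5 was above its group in Mmp12 (9.81 FPKM), Ccl2 (27.4 FPKM) and the chemokine and oxidative stress lists (4.38 and 6.43), and below it in Scand1 (22.8 FPKM). Silica day 28 replicate 2 had 213 FPKM of Cebpb (45.6 to 62.6) and 13.8 FPKM of Angptl4.

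Saline day 14 replicate 3 was above its group in Aqp1 (324 FPKM), Ccl2 (29.1 FPKM) and Mmp12 (6.8 FPKM), replicate 2 in the endothelium list (6.61) and replicate 1 in H1fx (8.57 FPKM). Saline day 28 replicate 5 was above its group in Mmp12 (8.49 FPKM) and H1fx (13.5 FPKM), and saline day 28 replicate 6 was below it in Col1a1 (36.1 FPKM) and the lysosome and oxidative stress lists (5.33 and 5.84). Silica day 14 replicate 5 had 21.2 FPKM of Timp1, above its group, and 4.26 for the complement list, below it. Silica day 14 replicate 4 had 245 FPKM of Acta2 and 60.6 FPKM of Rn7sl1, a structural RNA, both above its group.

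The silica effect at day 28 differed from that at day 14, by the test of the difference itself, in 18 named genes. The log2 differences were 0.92 in Col1a1, 0.915 in Col3a1, 3.94 in Myh9, 3.11 in Pcdhgc3, 3.05 in Lrrc8a, 2.72 in Palm2, 2.34 in Irf9, 2.33 in Aqp1, 1.97 in Lrrc4 and 1.97 in Praf2. Negative differences were -3.69 in RF00030, -2.32 in Dbp, -2.18 in RT1-N2, -2.07 in Mlc1, -1.96 in Scand1, -1.91 in Tef, -1.81 in Gng13 and -1.77 in Cracr2b. None of the 18 was called by limma-trend without the 3 saline day 28 libraries over 5% mitochondrial reads, where 8 genes were called in all. Each kept its direction there. In the order given, the positive differences were then 0.803, 0.744, 3.12, 2.53, 2.66, 2.48, 2.51, 1.9, 1.86 and 1.45. The negative ones were -1.81, -2.24, -2.16, -1.66, -2.005, -1.52, -1.597 and -1.577.

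The effect also differed in 8 lists. The median log2 difference of the members was 0.812 in extracellular matrix, 0.558 in metalloproteinases, 0.245 in TGF-beta signalling, 0.241 in alveolar type 1 cell, 0.6 in cell cycle, 0.317 in sterol synthesis, 0.358 in fatty acid synthesis and 2.35 in cardiac muscle. None of these lists passed camera with an estimated correlation.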

How the results depend on the processing

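The alternatives chosen after the data had been seen were voom on recovered reads, median rescaling, the 2 covariates, the length correction, the saline group of the other day and the sets of libraries left out. The other alternatives were fixed in advance. Of those, the other count-based scaling, the other count-based test and the surrogate variable had been laid out for original counts and were not run. The fit of only the groups compared has no version for the difference of the silica effects. Unless a cause is given, the cause of a change was not tested.

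Under the alternatives fixed beforehand, single libraries left out aside, 4259 values of named genes kept direction and side of the threshold, 340 lost the call, 47 gained one and 0 reversed; for lists these were 925, 40, 21 and 0. Under the later ones they were 5441, 729, 278 and 8 for genes and 1208, 72, 54 and 26 for lists.

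The pseudocount of 0.1 and median rescaling kept every count of calls within 1.5 times. Without a filter 13 lists differed between the silica effects in place of 8 and 0 genes were called in silica over time. With the stricter filter 7 lists passed at day 28 in place of 12. With the replicate block the difference of the silica effects had 1227 calls and silica over time 0. An adjusted p under 0.01, a stricter threshold by construction, left 363 genes at day 14 (289 higher), 341 at day 28 (184 higher), 92 for the difference, 0 in silica and 2162 in saline over time, 72 shared calls, and 4, 5 and 10 lists at day 14, at day 28 and in saline. The fit of only the groups compared gave 580 genes at day 28 (313 higher, 267 lower), 0 in silica over time, 95 shared calls and 6 lists at day 14.

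Voom on recovered reads called 0 genes in silica over time, as did the length correction, where limma-trend gave 1838 genes at an unadjusted p under 0.05. The length correction gave 546 higher and 201 lower genes at day 14 in place of 564 and 347. The first residual component gave 1968 calls at day 14 (971 higher, 997 lower), 4662 at day 28, 4147 for the difference, 0 in silica over time, 332 shared calls and 13 lists for the difference. It was taken from the residuals of the same fit. By construction it leaves the log2 changes as they were and lowers the spread, so that more calls are no support for the result.

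With the mitochondrial share as a covariate 1701 genes were called at day 14 (810 higher, 891 lower), 21 at day 28 (19 higher), 7 for the difference, 0 in silica and 12 in saline over time, with 19 shared calls and 6 lists at day 28 and 6 in silica over time. At day 28 Itga8 (-0.0751), Csf1r (-0.0161), ND1 (0.0358), ND5 (0.0736) and COX2 (0.0471) reversed, and in saline over time Lamp2 (0.053), Adgre1 (0.111) and ND1 (-0.0603). The mean changes relative to all genes that reversed at day 28 were those of metalloproteinases (-0.0686), TGF-beta (-0.0208), alveolar type 2 cell (-0.0755), endothelium (-0.0936), alveolar fibroblast (-0.0867), complement (-0.195) and mitochondrially encoded genes (0.107). For the difference of the effects the inflammasome list reversed (-0.253). In saline over time the inflammasome (0.271), interferon (0.224), T and NK cell (0.241), alveolar type 2 cell (0.25), endothelium (0.0794), complement (0.188) and mitochondrially encoded (-0.18) lists reversed. The share is highest in the saline day 28 group, so that this covariate also removes part of the group difference.

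Without the libraries in doubt, 3 saline and 1 silica, 1634 genes were called at day 14, 56 at day 28 (46 higher), 10 for the difference, 0 in silica and 601 in saline over time (255 higher), with 42 shared calls and 5 lists in silica over time. Reversed lists were T and NK cell at day 28 (-0.211), for the difference (-0.322) and in saline (0.206), complement at day 28 (-0.0348) and in saline (0.0282), and skeletal muscle in silica (-0.0138). Without the 3 saline day 28 libraries over 5% mitochondrial reads 60 genes were called at day 28 (43 higher), 8 for the difference, 0 in silica and 361 in saline over time (161 higher), with 40 shared calls and 7 lists at day 28. T and NK cell reversed at day 28 (-0.195), for the difference (-0.306) and in saline (0.206), and complement at day 28 (-0.0833) and in saline (0.0282). Without the other 3 saline day 28 libraries, a loss of the same number, 6345 genes were called at day 28, 5237 for the difference and 0 in silica over time, with 19 lists at day 28 and 17 for the difference. The loss of calls therefore did not come from the number of libraries alone.

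Against the saline group of the other day, 408 genes were called for silica at day 28 (283 higher, 169 shared with the 2872) and 3426 for silica at day 14 (1347 higher, 352 shared with the 911). Of the main calls, 1263 of 2872 at day 28 and 173 of 911 at day 14 changed sign. Values of single genes under this setting are not listed, a choice made after they had been seen. Camera with an estimated correlation called 0 lists at day 14, 0 at day 28, 0 for the difference, 0 in silica and 0 in saline over time. Fry called 3, 4, 3, 1 and 10.

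With each library left out in turn, the genes called ranged from 576 to 1073 at day 14, from 993 to 4429 at day 28, from 1062 to 3286 for the difference, from 0 to 2 in silica and from 3682 to 6346 in saline over time, and the shared calls from 114 to 222. Lists ranged from 5 to 10, 8 to 17, 7 to 12, 4 to 16 and 14 to 17. The day 28 count was lowest without saline day 28 replicate 2 and highest without saline day 28 replicate 5. Of the list values 1 reversed, that of skeletal muscle in silica over time, from -0.0138 without silica day 28 replicate 1 to 1.56. The lowest library had 55.06 M recovered reads, and an effect of depth on rarer transcripts was not tested.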

Other observations

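The tests of age, airway, single-exon genes and both clock explanations were chosen after the result was seen; those of the mitochondrial share, of length at day 14 and of other splits of the samples were written before. That of structural RNA was written before its result but after the calls and the percents were seen. A test of transcript length for the saline day 28 group was dropped after its result, in which 4996 genes were called in saline over time and 81.1% of the main calls were called again.

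Saline lungs at day 28 differed from those at day 14 in 5255 genes. Age alike in both treatments was argued against for these calls as a set. Genes called in saline had a median change of -0.0213 in silica in the saline direction, where their median size in saline was 0.54. In silica their mean was -0.00297 (SE 0.0799, exact permutation p = 0.972). Without the high-mitochondrial saline libraries 361 genes were called and the test was not repeated. Of lists past camera in both treatments there, medians moved alike in ciliated (0.524 in saline, 0.396 in silica) and endothelium (-0.266, -0.227). Medians of the mesothelium, mast cell, type 1 and mitochondrially encoded lists also had the same sign in both. The matrix medians shared their sign but not their size, at -0.798 in saline and -0.127 in silica. Cell cycle and cardiac medians went opposite ways. A shared effect of age on some genes stays open. A greater share of airway tissue with a like loss of every other part was also argued against. The matrix list fell relative to the macrophage list by a log2 of -0.913 (SE 0.107, exact permutation p = 0.00216). As this pair of lists was chosen after the result was seen, the p is no independent support. An unequal loss of the other parts was not tested. A higher mitochondrial read share is a candidate explanation: with it as a covariate 12 genes were called, the median change went from 0.54 to 0.286 and its SE from 0.146 to 0.192, but the share is partly confounded with the group. Other library measures differed as well and were not tested as causes: depth, summed FPKM and the share of the 10 most abundant genes (exact permutation p = 0.00216 each) and structural RNA (0.0303); these stay open, as do handling of the tissue, the health of the saline animals, a library batch and an effect of age that silica altered.

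At day 14 clock genes differed between silica and saline. Genes set beside Dbp averaged 0.849 over 10 and those set beside Arntl -0.481 over 4. The exact rank permutation p of 1 set against the other was 0.024, but the sets hold the called genes that prompted the test. The test also treats genes that move together as independent, and gives each set 1 peak time, which was not checked. Among the 6 and 3 genes not called the exact rank permutation p was 0.167. Per1 and Per2, at -0.88 and -0.115, went against the rest of their set. As genes of a set may peak at different times, this does not count against time of day. Lungs taken at another time of day were neither supported nor excluded. A lasting effect of silica on Dbp was argued against, since its log2 change at day 28 was 0.108; Nr1d1 and Nr1d2 had 0.73 and 0.977 at day 28 and were called. The labels give no time of collection, which may be confounded with the group, and it stays open beside an effect of silica limited to day 14.

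The 911 calls at day 14 were set against 4 technical explanations. A trend with transcript length was argued against as the whole cause, with 747 calls after correction and 70.1% of the genes called again. With the mitochondrial share as a covariate there were 1701 calls and 100% were called again. However, that share was 2.17% in silica and 2.50% in saline at day 14 (exact permutation p = 0.26). The covariate could therefore remove little of a day 14 difference, and the larger count is no support for the result. The percent of reads on structural RNA was 0.854 ± 0.414 in silica and 0.443 ± 0.161 in saline (SD, n = 6; exact permutation p = 0.0498), and with it as a covariate 911 genes were called too, with 73.7% called again, which argues against it as the whole cause. Uneven recovery of GC-rich single-exon transcripts could not be decided: such genes had a median change of 0.221 at day 14, with 11 of 16 higher and a camera p of 6.83e-04 (0.0205 with an estimated correlation), which goes with it, but only 16 of the 29 listed were tested and GC content cannot be computed without a genome. Summed FPKM also differed (exact permutation p = 0.0411) and was not tested as a cause, and the biological explanation, the silica treatment, stays a hypothesis.

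The libraries were also divided in other ways, 100 divisions per comparison with the real one included, and the genes called were counted. At day 14, 1 of 100 gave as many, the real one with 911 against at most 11 in the others. That is the smallest share that 100 divisions can give, and it speaks against chance without excluding it. At day 28, 2 of 100 did, with 2872 in the real one and 2978 in the highest other, which exchanged saline replicate 5 and silica replicate 2. The difference of the silica effects had 2 of 100, with 2071 and 4208, and saline over time 2 of 100, with 5255 and 5594, the latter exchanging replicate 5 of the 2 days. In each of these 3 another division called more genes than the real one. At day 28 and in saline over time, 2 of 100 speaks against chance but does not exclude it. For the difference the days were exchanged within each treatment, which assumes no effect of day in either. Saline alone had 5255 calls between the days, so that this share cannot decide whether the silica effects differed by chance. The high divisions at day 28 and in saline all moved saline day 28 replicate 5, which points to a structure of the samples other than their groups. In silica over time 13 of 100 gave as many as the 1 gene called, with 4 in the highest other, so that chance cannot be excluded.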
